A study of Drosophila melanogaster with 12 samples.

How the data were processed

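The samples were type II neuroblasts of the Drosophila melanogaster larval central nervous system, at 4 ages (24, 36, 50 and 84 h after larval hatching) with 3 libraries per age, 12 in all. Per the labels, larvae were synchronised within 2 h and kept at 25 °C, 30 brains were dissected, tissue was digested with pronase and dispase for 30 min, GFP-labelled cells were sorted 10 at a time by a robotic sorter, and total RNA was drawn from about 100 pooled cells. The labels give 93 to 132 sorted cells per library, amplification with the Ovation RNA-Seq System V2, an Encore library kit, and the same volume and mix of ERCC spike-in RNA in every library. The driver that labels the cells is not given in the sources used here. The labels do not say whether libraries of one age came from separate dissections, so p-values measure the spread between these libraries, which may be technical.

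The authors deposited 2 tables. The first holds, from the values in it, counts per gene symbol and ERCC RNA as deposited, with no scaling; its 15432 rows are 15340 genes and 92 ERCC RNAs. The second holds TPM by the authors, deposited for 15340 rows and summing to 1000000 in each library, without ERCC rows. Per the submitters' processing notes the tools were CASAVA, cutadapt 1.7.1, Bowtie2 2.1.0, STAR 2.4.0i and HTSeq 0.6.1p1, and the builds mm10, dm3 and BDGP5 were named. The role of each tool and build, the strand setting, the read filters and the lengths or counts behind the TPM are not given in the sources used here. The reference at hand was a later build, so no coordinates are reported, and values of overlapping, antisense or paralogous genes are uncertain because the strand setting is not stated. Gene identifiers came from the TPM table for 6495 symbols and from a table of current symbols for 6190, and 2655 symbols were left without one; 15148 symbols stand in both tables. Of the TPM rows, 129 share a symbol with another row and 1 has no values.

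Gene counts per library ranged from 4512102 to 8391731, with ERCC counts kept apart. A floor of 3 counts corresponds to 0.357 to 0.665 CPM (counts per 1000000 gene counts), depending on the library. Intervals and floors cover counting error only, since the libraries were amplified and carry no molecular identifiers. Between libraries of one age the chi-square per degree of freedom, over genes with at least 20 counts, was 10.69 to 48.11, and Spearman's rho over all genes, which are not independent replicates, was 0.92 to 0.949. In these libraries 2616 genes had no count.

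Differences were tested with edgeR 4.0.16 (TMM factors, filterByExpr by age, robust quasi-likelihood fit) in R 4.3.3 on all 12 libraries together, with 8 residual degrees of freedom. The filter kept 7978 genes with 99.85% of the gene counts, and the biological coefficient of variation was 36.2%. There were 5 contrasts, namely 36 h against 24 h, 50 h against 36 h, 84 h against 50 h, 84 h against 24 h, and the mean of 36 and 50 h against the mean of 24 and 84 h, and an F test for any difference between ages. All p-values are two-sided and adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Levels are mean CPM with the TMM-adjusted library sizes, ± SD over libraries. Log2 fold changes (log2FC) are given ± SE, the SE being the size of the change divided by the square root of its F statistic.

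Fixed gene lists, 24 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and contrasts, and beside it with an estimated correlation and with fry. The lists were larval neuroblast temporal factors, type II neuroblast and general neuroblast identity, intermediate progenitor markers, neuron markers, glia markers, hemocyte and fat body markers, muscle markers, optic lobe and eye disc markers, male dosage compensation, ecdysone response, cytosolic ribosomal proteins, ribosome biogenesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, glycolysis, DNA replication and G1/S, mitosis and G2/M, Notch signalling, asymmetric division machinery, heat shock and dissociation stress, Polycomb and trithorax, insulin and TOR signalling, axon guidance and cell adhesion, and RNA-binding regulators of translation and decay. The table holds 0 mitochondrially encoded genes, so 23 lists were tested in 5 contrasts, giving 115 tests. Some genes are members of several lists, as Imp, Syp and lin-28 are of the temporal and the RNA-binding lists. Fry asks whether a list's genes move one way on balance, or in its mixed form either way, and does not compare them with other genes.

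The rule for named genes took, for each contrast, the 8 genes that rose and the 8 that fell most (4 and 4 for the middle-against-ends contrast) among those past the threshold whose groups did not overlap and whose higher mean was at least 10 CPM, leaving out symbols that are only a CG or CR number. It added the temporal factors, up to 4 members of each list with a called test or at least 3 called members, and repo, elav, ase, erm, roX1 and roX2. Of the genes that this rule gave, the text describes a part, chosen after the values were seen with preference for calls kept in every leave-out of 1 library. The design, the contrasts, the lists, this rule and the alternatives were chosen before the data were examined, except where stated.

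The gene counts per ERCC count per sorted cell were compared between ages with a two-sided exact permutation test of the F statistic on log2 ratios. Alternatives were other scaling factors (DESeq2 1.42.0 size factors, upper quartile, ERCC totals, ERCC totals times sorted cells), other tests (DESeq2, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), glmTreat against a 2-fold change), no filter on low counts and a filter at 10 CPM in 3 libraries, the replicate number as a block, the number of sorted cells as a covariate, fits of only the 2 ages compared, and leaving out each library in turn. Where a leave-out leaves 2 libraries at an age, the fit still pools its spread over all ages. Alternatives added after seeing the data were fits without the 3 most abundant RNAs, with counts thinned to the shallowest library, without 84 h replicate 1 (also among the planned leave-outs), and without 24 h replicates 1 and 2 together.

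The pipeline was tested on simulated data made from these counts, with known changes given only to genes with a mean of at least 10 CPM. Of genes changed 2-fold, 49 to 52% were called in the contrasts of 3 against 3 and 77% in the contrast of 6 against 6, and of genes changed 4-fold 87 to 99%. None was called in the wrong direction, and 1 to 5.4% of calls were false. A changed list was called in all 5 contrasts by each set test. Of 115 tests of unchanged lists 2 were called at the preset correlation, 1 with an estimated correlation and 5 by fry. Simulated genes were drawn independently of each other, so these rates do not cover lists whose members move together. Data handling and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.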

Results

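RNA from small pools of sorted type II neuroblasts, the stem cells of the fly brain that divide through intermediate progenitors, was sequenced at 24, 36, 50 and 84 h after larval hatching, with 3 libraries per age. The series title speaks of temporal factor gradients triggered by Seven-up, so the comparisons ask which transcripts, temporal factors first, differ between the ages. The 24 h libraries held 8391731, 7738401 and 4894369 gene counts. The 36 h libraries held 5241945, 5129350 and 4668709, the 50 h libraries 5765181, 4764110 and 4512102 and the 84 h libraries 5677224, 5333622 and 4849110. Between 8953 and 10797 genes had at least 1 count in a library. A few RNAs took a large part of each library. The long noncoding RNA cherub, listed as CR43283 and singled out after its values were seen, took 11.5% ± 2.30 of the gene counts at 24 h (SD, n = 3 here and below). Its share was 16.3% ± 3.18 at 36 h, 11.4% ± 1.02 at 50 h and 5.63% ± 1.95 at 84 h. Imp took 5.03% ± 0.87 at 24 h. The 18S rRNA pseudogene CR41602 took 7.78 to 10.5% on average at the 4 ages and the 2S rRNA pseudogene CR40677 5.35 to 6.56%.

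The temporal factors changed over the whole course. Imp (FBgn0262735), an RNA-binding protein of young neuroblasts, went from 59080 ± 15300 CPM at 24 h through 35450 ± 6910 at 36 h and 7149 ± 833 at 50 h to 228.1 ± 49.9 at 84 h. Syp (FBgn0038826), an RNA-binding protein of old neuroblasts, went the other way, with 603.3 ± 130, 11450 ± 4750, 28560 ± 3020 and 25600 ± 6540 CPM. The orphan nuclear receptor svp (FBgn0003651), which the title names, was highest at 24 h with 662.9 ± 128 CPM and stood at 108.1 ± 15.5 at 50 h. The zinc-finger factor chinmo (FBgn0086758) had 1934 ± 411, 1497 ± 228, 1091 ± 162 and 499.8 ± 212 CPM. The ecdysone-response factors br (FBgn0000210) and EcR (FBgn0000546) peaked at 50 h, with 850.9 ± 40.7 and 292.8 ± 42.9 CPM, as did the zinc-finger factor cas (143.1 ± 72.6) and the Sox factor D (76.26 ± 22.1). Eip93F (FBgn0264490), an ecdysone-induced factor, had 5.613 ± 2.74 CPM at 24 h and 703.2 ± 164 at 84 h. Of the 7978 genes tested, 1556 differed between ages, 2553 at an unadjusted p under 0.05. Of the 1556, 702 had their highest mean at 24 h, 167 at 36 h, 265 at 50 h and 422 at 84 h, and the means rose at every step for 235 and fell at every step for 331. These counts rest on TMM scaling and were not redone under scaling to ERCC totals. Under that scaling 2343 genes were called as higher and 34 as lower at 84 h than at 24 h. Of the temporal list's 13 tested members, Kr alone did not pass the test for any difference between ages (adjusted p = 0.363), with 14.91 ± 11 CPM at 24 h and 2.047 ± 2.03 at 84 h.

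**Figure D1:**
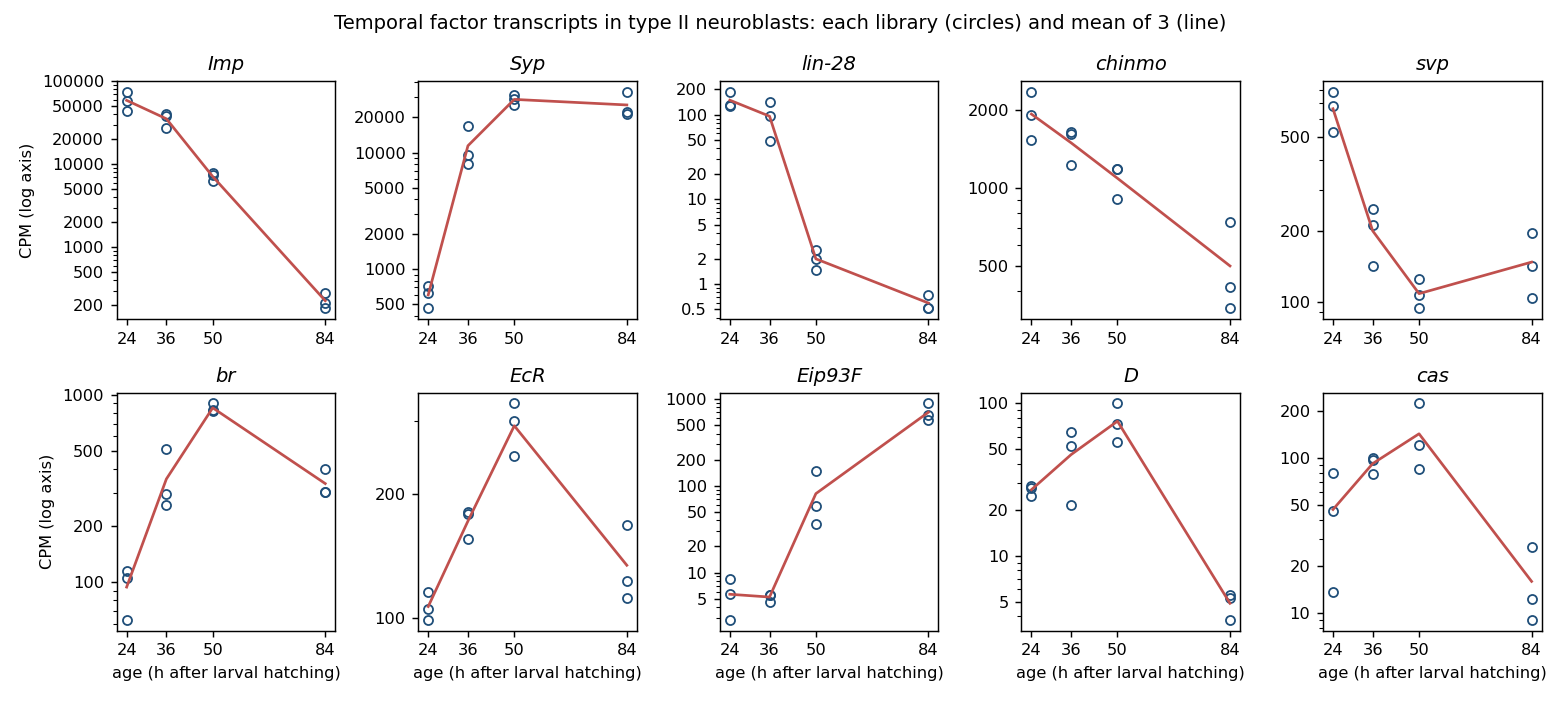
CPM on a log axis against age in hours after larval hatching for 10 temporal factors, with circles for the 12 libraries and a line through the mean of 3 libraries per age. Imp drops from 59080 to 228.1 CPM while Syp climbs from 603.3 to 25600, and br, EcR, D and cas have their highest mean at 50 h.

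The comparison of 36 h with 24 h asked what changed first. Syp rose 19-fold (log2FC 4.25 ± 0.27, adjusted p = 1.97e-09) and br rose 3.77-fold (1.92 ± 0.24, adjusted p = 9.79e-05), while svp fell 3.32-fold (-1.73 ± 0.23, adjusted p = 0.000127). Imp was 1.67-fold lower without passing the test (-0.74 ± 0.20, adjusted p = 0.0868), as EcR was 1.61-fold higher (0.69 ± 0.18, adjusted p = 0.0629). Leaving out 24 h replicate 3 (0.0226) or 84 h replicate 1 (0.0354) brought Imp past the threshold, with a range over all alternatives of 0.00395 to 1. Here and below such ranges for single genes include glmTreat against a 2-fold change, which asks for a larger change. For a change near or under 2-fold a high upper end can come from that test alone. EcR passed without 84 h replicate 1 (0.0327, range 0.0213 to 1). Of 13 temporal factors 2 rose and 1 fell, 5 and 4 adjusted over the list alone. The list test was not called (adjusted p = 0.406), with a median of -0.06 and a mean of 0.32. The forkhead factor gene fd102C rose from 3.678 ± 2.82 to 31.5 ± 11.8 CPM, and the zinc-finger factor genes elB and chn rose 3.63-fold and 5.79-fold. The serine protease homologue mas rose 3.55-fold, from 38.55 ± 9.14 to 137.2 ± 45.2 CPM. CrebA, a regulator of secretory genes, fell 3.7-fold (-1.89 ± 0.31), Lin29 fell 3.27-fold from 163.3 ± 12.1 CPM, the dystrophin gene Dys fell 2.57-fold from 191.3 ± 30.5 CPM. The Snail-family factor gene scrt fell 4.64-fold. Of these, chn was not called without 36 h replicate 3 (0.07, range over all alternatives 5.38e-05 to 0.259) and was 11.4-fold higher without 24 h replicate 2, and scrt not without 36 h replicate 1 (0.06) or 36 h replicate 2 (0.0606, range 2.66e-05 to 0.57).

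Several lists were called between 24 and 36 h at the preset correlation, none of them with an estimated correlation. Over all comparisons 33 list tests were called, against a median of 18 under shuffled ages, so single list calls are weak evidence here and below. DNA replication and G1/S genes rose as a group (list median log2FC 0.27, above 0 in 30 of 35 members, adjusted p = 0.000291), though the adjusted p = 0.129 with an estimated correlation and 0 members passed singly, also when adjusted over the list alone. Members such as E2f (578.1 ± 67.7 to 838.7 ± 56.0 CPM, adjusted p = 0.128) and Mcm6 (92.02 ± 15.0 to 138.7 ± 34.3, adjusted p = 0.152) give the size. Mitosis and G2/M genes rose as a group (median 0.18, 25 of 34 above 0, adjusted p = 0.00851; adjusted p = 0.188 with an estimated correlation). CycA, a cyclin that drives entry into mitosis, rose 1.78-fold to 435.9 ± 54.5 CPM as the 1 member called, with 4 adjusted over the list alone. CycB was 1.5-fold higher without passing (adjusted p = 0.0627), and passed without 24 h replicate 3 (0.0367) or 84 h replicate 1 (0.0472, range over all alternatives 0.0129 to 1). The heat shock and dissociation stress genes fell as a group (median -0.50, turned to 0.39 with ERCC totals, 22 of 23 members below 0, adjusted p = 2.77e-05; adjusted p = 0.402 with an estimated correlation). Its 1 called member, the Fos homologue kay, fell 2.06-fold, with 2 members adjusted over the list alone. It was not called without 24 h replicate 2 (0.158), 36 h replicate 2 (0.157) or 36 h replicate 3 (0.137, range over all alternatives 0.000264 to 1). Axon guidance and cell adhesion genes fell as a group (median -0.23, turned to 0.63 with ERCC totals, adjusted p = 0.00146; adjusted p = 0.402 with an estimated correlation), with 3 of 37 members down and 1 up, and 5 and 1 adjusted over the list alone. The teneurin gene Ten-m fell 3.01-fold, from 229.7 ± 38.3 to 76.22 ± 10.1 CPM. The Slit ligand gene sli fell 2.09-fold but was not called without 24 h replicate 2 (0.0658) or 36 h replicate 3 (0.084, range over all alternatives 2.66e-05 to 1). The other 2 called members were Fas3 and 18w. Fas3 lost its call in 10 of the 12 leave-outs, with an adjusted p up to 0.235 without 36 h replicate 3 (range over all alternatives 2.98e-15 to 0.744). The 18w call was lost in 6, with an adjusted p up to 0.171 without 36 h replicate 1 (range 0.00117 to 0.273). Ribosome biogenesis genes rose (median 0.24, 0 of 22 members called, 0 adjusted over the list alone, adjusted p = 0.029; adjusted p = 0.402 with an estimated correlation). Notch signalling genes fell (median -0.45, turned to 0.51 with ERCC totals, 0 of 23 called, 0 over the list alone, adjusted p = 0.0257; adjusted p = 0.402 with an estimated correlation). Insulin and TOR genes fell (median -0.22, turned to 0.63 with ERCC totals, 0 of 17 called, 0 over the list alone, adjusted p = 0.0285; adjusted p = 0.308 with an estimated correlation). The ribosome biogenesis call ended without 24 h replicate 2 (0.0828) or 36 h replicate 3 (0.152, range 0.00914 to 0.152). The Notch call ended without 24 h replicate 2 (0.158), 24 h replicate 3 (0.0599), 36 h replicate 1 (0.0531) or 36 h replicate 2 (0.0645) and under scaling to ERCC totals (0.159, range 0.00586 to 0.159). The insulin and TOR call ended without 24 h replicate 1 (0.0927) or 36 h replicate 3 (0.102) and under scaling to ERCC totals (0.845, range 0.0163 to 0.845).

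In all, 72 genes passed between 24 and 36 h, 36 up and 36 down, 55 of them by at least 2-fold, and 1170 genes had an unadjusted p under 0.05. The 3 later libraries did not overlap the 3 earlier ones for any of the 72, but passing a test on the same libraries selects for this, so the 10% that chance gives for unselected genes is no measure here or below. The count was 40 without 24 h replicate 2, 180 without 24 h replicate 3, 29 without 36 h replicate 3 and 21 with the number of sorted cells as a covariate. The sorted cells numbered 93 to 101 at 24 h and 105 to 132 at 36 h. With that covariate 10 of the 17 called genes named here, svp, elB, CrebA and CycA among them, were not called. Of the named genes 9 of 16 were not called on the TPM and 11 of 17 not under scaling to ERCC totals. The TPM called 27 up and 7 down, and scaling to ERCC totals 20 up and 0 down.

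Between 36 and 50 h the RNA-binding factors lin-28 and Imp fell. The fall of lin-28 was 48.7-fold, from 96.03 ± 46.4 to 1.982 ± 0.533 CPM (log2FC -5.61 ± 0.38, adjusted p = 2.22e-09), and Imp fell 4.96-fold (-2.31 ± 0.21, adjusted p = 3.27e-07). Syp rose 2.49-fold (1.32 ± 0.24, adjusted p = 0.00193), br 2.4-fold (1.26 ± 0.23, adjusted p = 0.00221) and Eip93F 15.4-fold (3.95 ± 0.56, adjusted p = 0.0031), or 9-fold without 50 h replicate 2. Of 13 tested temporal factors 4 rose and 3 fell, 6 and 3 adjusted over the list alone, and the list test was not called (adjusted p = 0.692). Among the 7, EcR rose 1.7-fold (0.77 ± 0.18) but was not called without 36 h replicate 2 (0.0516), 36 h replicate 3 (0.0655), 50 h replicate 1 (0.0532) or 50 h replicate 2 (0.0841, range over all alternatives 0.00245 to 1). The gene svp fell 1.85-fold (-0.89 ± 0.23), which became an uncalled 0.16 under scaling to ERCC totals. It was not called without 36 h replicate 1 (0.0799), 36 h replicate 2 (0.153), 50 h replicate 1 (0.116) or 50 h replicate 3 (0.0866, range 0.000117 to 1). Genes that rose were nerfin-1, a zinc-finger factor of early neuronal differentiation, 26.2-fold (0.8948 ± 0.68 to 24.34 ± 4.88 CPM), and Gr63a, a subunit of the carbon dioxide receptor, 23.2-fold. A gene of Fat signalling, lft, rose 9.11-fold. E23, an ecdysone-inducible ABC transporter, fell 25.2-fold from 535.6 ± 223 CPM. The organic cation transporter genes Orct and Orct2 fell 12.2-fold and 5.85-fold, the laminin gene LanB1 10.7-fold, the esterase gene alpha-Est9 7.34-fold and the T-box factor gene bi 5.49-fold. Single libraries moved some of these folds by over 1.5 times. The rises were 42.2-fold for nerfin-1 without 36 h replicate 3 and 18.1-fold for lft without 36 h replicate 1. The falls were 56.1-fold for E23 and 10.1-fold for bi without 50 h replicate 2, 6.63-fold for Orct without 36 h replicate 3, and 20-fold each for Orct and LanB1 without 50 h replicate 1.

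Glycolysis genes rose between 36 and 50 h, with 9 of 15 members up and 0 down (12 and 0 adjusted over the list alone). The list median log2FC was 0.71, with 14 members above 0 (adjusted p = 1.92e-11; adjusted p = 0.0997 with an estimated correlation). The phosphoglycerate mutase gene Pglym78 rose from 119.9 ± 4.38 to 253.6 ± 20.9 CPM and the triose phosphate isomerase gene Tpi from 84.87 ± 5.50 to 149.4 ± 9.90. The count of 9 fell to 2 without 36 h replicate 2, 3 without 50 h replicate 1, 4 without 50 h replicate 2, and 5 without 36 h replicate 3 or 50 h replicate 3. Mitosis and G2/M genes rose as well, with 8 of 34 members up and 0 down (9 and 0 adjusted over the list alone), 30 above 0 and a median of 0.29 (adjusted p = 8.32e-07). This call held with an estimated correlation (adjusted p = 0.046). The Cdc25 phosphatase gene stg rose 2.46-fold to 840.3 ± 127 CPM, CycB 2.1-fold to 454.1 ± 40.1, the spindle gene asp 2-fold to 319.7 ± 23.4 and CycA 1.8-fold to 783.1 ± 92.1. Beside these groups, hemocyte and fat body markers had 6 of 6 members above 0 and a median of 0.98, with 0 members called (camera adjusted p = 0.107, fry adjusted p = 0.00777). Their median was 1.50 without 36 h replicate 2, where camera called them (adjusted p = 0.0453, range 0.0453 to 0.247), and 0.65 without 50 h replicate 1. Cytosolic ribosomal protein genes fell as a group, with 85 of 86 members below 0 and a median of -0.42, though the median turned to 0.67 under scaling to ERCC totals (adjusted p = 9.78e-23; adjusted p = 0.402 with an estimated correlation). Relative to the median of all genes it was -0.45, and -0.43 under that scaling, which moves all genes by about the same amount. RpL22 (-0.71 ± 0.15, 261.7 ± 14.6 to 159.8 ± 12.7 CPM) and RpLP0 (-0.60 ± 0.14, 560.0 ± 10.5 to 368.9 ± 9.31 CPM) were the 2 members that fell singly. Adjusted over the list alone 54 fell and 1 rose. RpLP0 was not called without 36 h replicate 2 (0.0507), 50 h replicate 1 (0.065) or 50 h replicate 3 (0.0501, range over all alternatives 5.3e-05 to 1). The count of 2 became 12 without 24 h replicate 2, 11 without 24 h replicate 3, 10 without 84 h replicate 1, and 1 without 50 h replicate 1 or 50 h replicate 3. RNA-binding regulators fell as a group (median -0.23, turned to 0.88 with ERCC totals, adjusted p = 0.00295; adjusted p = 0.599 with an estimated correlation). Of 23 members Imp, lin-28, shep and rin, the homologue of the stress granule protein G3BP, fell and Syp rose, 8 and 3 adjusted over the list alone. The fall of rin was 2.09-fold, from 1885 ± 331 to 903.7 ± 136 CPM, and the list's call ended under scaling to ERCC totals (0.0942, range 0.00102 to 0.0942). Nuclear oxidative phosphorylation genes rose (median 0.16, adjusted p = 0.0229; adjusted p = 0.639 with an estimated correlation), with CoVIb as the 1 member called of 21 and 1 adjusted over the list alone. That list call ended without 36 h replicate 1 (0.0978), 36 h replicate 2 (0.0746) or 50 h replicate 3 (0.0827, range 0.00408 to 0.0978). CoVIb was not called without 36 h replicate 1 (0.125), 36 h replicate 2 (0.153) or any 50 h library (0.134, 0.061 and 0.0724 for replicates 1, 2 and 3, range over all alternatives 0.00645 to 1).

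Among other genes named between 36 and 50 h, the Notch targets E(spl)m7-HLH and E(spl)malpha-BFM rose 7.41-fold and 9.04-fold, to 103.8 ± 50.9 and 35.02 ± 34.4 CPM. The Notch list was not called (2 of 23 up, 3 up and 3 down adjusted over the list alone, adjusted p = 0.39), and E(spl)malpha-BFM was 4.06-fold higher and not called without 50 h replicate 3 (0.0968, range over all alternatives 4.18e-08 to 0.233). The teneurin genes Ten-a and Ten-m fell 3.09-fold and 2.99-fold. In all, 339 genes passed, 150 up and 189 down, 186 of them by at least 2-fold, with groups that did not overlap in 334 (10% by chance for unselected genes), and 1387 genes had an unadjusted p under 0.05. The TPM called 177 up and 71 down and scaling to ERCC totals 144 up and 4 down. The count was 157 without 36 h replicate 2, 186 without 50 h replicate 1, 211 without 50 h replicate 2 and 199 without 50 h replicate 3. Of the 30 genes named here, 12 were not called and 4 more turned direction under scaling to ERCC totals.

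Between 50 and 84 h 6 of 13 temporal factors fell and 1 rose. Imp fell 31.3-fold (log2FC -4.97 ± 0.24, adjusted p = 1.5e-12), D 15.6-fold (-3.96 ± 0.36, adjusted p = 2.23e-07), br 2.54-fold (-1.34 ± 0.23) and EcR 2.18-fold (-1.12 ± 0.18), while Eip93F rose 8.7-fold (3.12 ± 0.47, adjusted p = 0.00532), or 14.9-fold without 50 h replicate 2. Syp was level within its spread (-0.16 ± 0.23, adjusted p = 0.867). Adjusted over the list alone 8 fell and 1 rose, with a list median of -1.13 (adjusted p = 3.62e-08). The list call held with an estimated correlation (adjusted p = 0.046). Among the 6, chinmo fell 2.18-fold but was not called without 84 h replicate 3 (0.0588, range over all alternatives 3.48e-08 to 1). The factor cas fell 8.87-fold from 143.1 ± 72.6 to 16 ± 9.32 CPM. It lost its call without 24 h replicate 2 (0.0806), 36 h replicate 3 (0.0579), 50 h replicate 2 (0.0976), 50 h replicate 3 (0.0692), 84 h replicate 1 (0.154), 84 h replicate 2 (0.0514) or 84 h replicate 3 (0.16, range 1.69e-33 to 0.305). Genes that rose were Mdr49, an ABC transporter, 24.3-fold, the laminin gene wb 24.1-fold and Adgf-A, an adenosine deaminase-related growth factor, 9.57-fold. CrebA rose 7.52-fold to 42.1 ± 2.83 CPM, and the noncoding RNA pncr002:3R 5.91-fold to 6907 ± 1580 CPM. The cuticle protein gene Ccp84Ab, at 0 counts in the 50 h libraries, was at least 21.5-fold higher at 84 h against a floor of 3 counts per library. Genes that fell were Oatp74D, an importer of ecdysone, 24.3-fold from 663.1 ± 82.1 CPM, CAP 11.6-fold, osp 9.57-fold and Sip1 9.46-fold from 247.2 ± 14.1 CPM. Without 84 h replicate 1 the falls were 43.7-fold for Oatp74D, 18.6-fold for CAP, 16-fold for osp and 14.4-fold for Sip1. The rises were 53.1-fold for Mdr49 without 50 h replicate 1 and 14.8-fold for Adgf-A without 50 h replicate 3. The wb fold rests on 16, 2 and 1 counts in 50 h replicates 1, 2 and 3, and without replicate 1 the fit gave 83.3-fold on the 3 counts left, too few to fix a size. Oatp74D was not called without 84 h replicate 2 (0.0514, range over all alternatives 1.09e-94 to 0.0514).

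The list of neuroblast identity genes fell as a group between 50 and 84 h (median -0.35, adjusted p = 0.0033, or 0.313 with an estimated correlation). It also holds nerfin-1, a factor of early neuronal differentiation, and pros and ase, which stand in the intermediate progenitor list too. The list test is thus no measure of neuroblast identity alone. Of 20 members tll, Sp1 and nerfin-1 fell, the last of which is no fall of neuroblast identity, with 6 down and 1 up adjusted over the list alone. The nuclear receptor gene tll fell 1.97-fold, from 298.9 ± 55.8 to 151.4 ± 38.1 CPM. Sp1 fell 1.7-fold but was not called without 50 h replicate 2 (0.106), 84 h replicate 2 (0.145) or 84 h replicate 3 (0.0783, range over all alternatives 0.00298 to 1). The fall of nerfin-1 was 4.37-fold but not called in 6 leave-outs (0.0557 without 36 h replicate 1, 0.142, 0.192 and 0.0899 without 50 h replicates 1, 2 and 3, 0.188 without 84 h replicate 1 and 0.214 without 84 h replicate 3, range 0.0057 to 0.786). DNA replication and G1/S genes fell as a group (median -0.30, 26 of 35 below 0, adjusted p = 5.07e-05; adjusted p = 0.0997 with an estimated correlation). CycE, the G1 cyclin, and RnrL, a ribonucleotide reductase subunit, fell singly, and 8 members fell adjusted over the list alone. CycE fell 2.02-fold, from 550.0 ± 121 to 272.5 ± 51.7 CPM. RnrL fell 1.6-fold but was not called in 6 leave-outs (0.0527 and 0.0501 without 36 h replicates 1 and 2, 0.0693 and 0.284 without 50 h replicates 1 and 3, 0.183 and 0.167 without 84 h replicates 2 and 3, range over all alternatives 0.0104 to 1). The mitosis list was not called (adjusted p = 0.0556), with CycA, stg and Cks30A down and feo up of 34, 6 and 1 adjusted over the list alone. CycA fell 1.7-fold to 461.1 ± 19.6 CPM and feo, a gene of the central spindle, rose 2-fold to 191.7 ± 38.5. Notch signalling genes fell as a group (median -0.53, adjusted p = 6.24e-05; adjusted p = 0.16 with an estimated correlation), 6 of 23 down and 0 up, 9 and 1 adjusted over the list alone. E(spl)m5-HLH, at 0 counts in the 84 h libraries, was at least 12.8-fold lower than at 50 h, and E(spl)malpha-BFM fell 7.38-fold. Both rest on 50 h replicate 3, without which the bound was 2.18-fold and the fall of E(spl)malpha-BFM 3.32-fold. E(spl)m5-HLH had 3, 8 and 85 counts in 50 h replicates 1, 2 and 3. No fallen Notch member kept its call in all 12 leave-outs. The count was 0 without 50 h replicate 3, 84 h replicate 1 or 84 h replicate 3, 2 without 84 h replicate 2, and 3 without 24 h replicate 2, 36 h replicate 3 or 50 h replicate 2. E(spl)malpha-BFM had an adjusted p of 0.244, 0.0599 and 0.0888 without 50 h replicate 3, 84 h replicate 1 and 84 h replicate 3 (range over all alternatives 5.23e-07 to 0.272). E(spl)m5-HLH had 0.27, 0.0764, 0.11 and 0.11 without 50 h replicate 3 and 84 h replicates 1, 2 and 3 (range 2.5e-05 to 0.27).

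Cytosolic ribosomal protein genes were slightly higher as a group at 84 h than at 50 h (median 0.14, turned to -0.29 with ERCC totals, 65 of 86 above 0, 0 called, 0 adjusted over the list alone, adjusted p = 0.00662; adjusted p = 0.822 with an estimated correlation). The call ended without 50 h replicate 2 (0.408) or 84 h replicate 2 (0.53) and under scaling to ERCC totals (0.667, range 1.21e-07 to 0.667). RNA-binding regulators fell as a group (median -0.13, adjusted p = 0.0233; adjusted p = 0.639 with an estimated correlation). Imp and shep fell of 23, with 4 down and 1 up adjusted over the list alone. That list call ended without 50 h replicate 2 (0.112), 84 h replicate 2 (0.0642) or 84 h replicate 3 (0.128, range 0.000792 to 0.128). The fall of shep, 1.59-fold, was not called without 50 h replicates 1, 2 and 3 (0.123, 0.052 and 0.087) or 84 h replicates 2 and 3 (0.163 and 0.149, range over all alternatives 0.00558 to 1). The ecdysone response list was not called (adjusted p = 0.153), with 5 of 17 down and 1 up, also when adjusted over the list alone, a median of 0.22 and a mean of -0.26. Besides EcR, br and Oatp74D the coactivator gene tai (2.36-fold) and Eip75B (1.89-fold) fell. Of the adhesion and guidance genes, Lac fell 2.73-fold, rst 4.95-fold and the netrin receptor gene unc-5 2.11-fold, in a list that was not called (5 of 37 down, 1 up, 5 and 2 adjusted over the list alone, median 0.01, mean -0.15, adjusted p = 0.774). The noncoding RNA roX1 fell 1.73-fold from 5427 ± 546 CPM but was not called without 50 h replicate 2 (0.052, range over all alternatives 0.000108 to 1). In all, 244 genes passed, 93 up and 151 down, 147 of them by at least 2-fold, with groups that did not overlap in 243 (10% by chance for unselected genes), and 1010 genes had an unadjusted p under 0.05. Scaling to ERCC totals called 5 up and 28 down, and 22 of the 33 called genes named here were not called there, while 9 of 31 were not called on the TPM. The count was 112 without 50 h replicate 2, 133 without 50 h replicate 3, 133 without 84 h replicate 2 and 121 without 84 h replicate 3.

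Over the whole span, 84 h against 24 h, Imp fell 259-fold (log2FC -8.02 ± 0.27, adjusted p = 8.27e-16) and lin-28 fell 237-fold from 148.5 ± 32.7 to 0.5962 ± 0.134 CPM (-7.89 ± 0.43, adjusted p = 1.03e-11). Syp rose 42.4-fold (5.41 ± 0.28, adjusted p = 1.17e-11) and Eip93F rose 128-fold (7.01 ± 0.60, adjusted p = 1.73e-05). The genes svp, chinmo and D fell 4.5-fold, 3.87-fold and 5.53-fold, and br rose 3.57-fold. The fall of grh, a transcription factor of late neuroblasts, was 1.57-fold (-0.65 ± 0.17, adjusted p = 0.00819), less than the shift of all genes under scaling to ERCC totals, where it turned to 0.86. EcR (adjusted p = 0.204) and cas (adjusted p = 0.131) did not pass, cas passing without 24 h replicate 1 (0.0123, range over all alternatives 1.95e-08 to 0.895). In the list of larval neuroblast temporal factors 6 of 13 fell and 3 rose, 6 and 3 adjusted over the list alone, with a median of -1.52 and a mean of -0.90. Camera at the preset correlation did not call the list (adjusted p = 0.0549; 0.402 with an estimated correlation), while fry called it as lower (adjusted p = 0.000591). Camera called it without 24 h replicate 1 (0.0331), 36 h replicates 1 (0.0457) or 2 (0.0355), 50 h replicates 1 (0.0437) or 3 (0.0412) or 84 h replicates 1 (0.0287) or 2 (0.0294), under scaling to ERCC totals (0.0177) and with the replicate block (0.0345, range 0.0177 to 0.0804). Other genes that rose were pncr002:3R, 27.8-fold from 248.4 ± 50.9 CPM, lft 31.3-fold, wb 30.2-fold, Arc1, a Gag-like protein gene, 20-fold to 128.3 ± 58.5 CPM, and the vacuolar ATPase subunit gene VhaM9.7-a 18.2-fold. Ccp84Ab had 223 counts at 84 h and 1 at 24 h, a ratio of 219 with a 95% counting interval of 38.9 to 8690. Genes that fell were E23, 238-fold from 723.7 ± 136 CPM, LanB1 33.4-fold, atilla 31.8-fold, osp 29.1-fold, the calcineurin gene CanB2 24.4-fold and the cytochrome P450 gene Cyp6a17 19.6-fold. Without 24 h replicate 2 Arc1 rose 39.7-fold and Cyp6a17 fell 11.1-fold, without 24 h replicate 1 atilla fell 18.8-fold, and without 84 h replicate 1 osp fell 48.8-fold. Few counts stand behind 2 of these folds, with 1, 12 and 3 for wb in 24 h replicates 1, 2 and 3, and 2, 1 and 8 for Cyp6a17 in 84 h replicates 1, 2 and 3. Leaving out 24 h replicate 2 for wb (71-fold) or 84 h replicate 3 for Cyp6a17 (47.2-fold on the 3 counts left) moved these by over 1.5 times.

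Metabolic and cell cycle lists were called as higher at 84 h than at 24 h at the preset correlation, none with an estimated correlation. Of 15 glycolysis genes 8 rose and Gapdh2 fell (8 and 1 adjusted over the list alone), with a median of 0.56 (adjusted p = 0.00158; adjusted p = 0.402 with an estimated correlation). Tpi rose 2.91-fold, Pglym78 1.94-fold and ImpL3, the lactate dehydrogenase gene, 3.89-fold from 170.8 ± 24.5 to 664.5 ± 184 CPM. Of 34 mitosis and G2/M genes 11 rose and Cks30A fell (14 and 1 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.00018; adjusted p = 0.0821 with an estimated correlation). CycB rose 3.14-fold, feo 3.31-fold and asp 2.34-fold. The count of 8 glycolysis genes was 5 without 84 h replicate 3. Nuclear oxidative phosphorylation genes rose (median 0.30, adjusted p = 0.0433; adjusted p = 0.639 with an estimated correlation), SdhC and CoVb singly of 21 and 0 adjusted over the list alone. This call ended without 24 h replicate 1 (0.0858), 24 h replicate 2 (0.21), 84 h replicate 2 (0.0671) or 84 h replicate 3 (0.0694, range 0.00547 to 0.21). Beside the groups that rose, hemocyte and fat body markers had 4 of 6 members above 0, a median of 0.86 and a mean of 1.89 (camera adjusted p = 0.282, fry adjusted p = 0.0026), the median being 2.45 without 24 h replicate 1 and 1.59 without 84 h replicate 2. The DNA replication list was not called (adjusted p = 0.375) with 6 of 35 up and 3 down, 7 and 4 adjusted over the list alone.

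Signalling, adhesion and RNA-binding lists were called as lower at 84 h than at 24 h at the preset correlation, none with an estimated correlation. Under scaling to ERCC totals the median of all genes moved by 1.48 on the log2 scale, so the list medians of this paragraph turned above 0 there, and they are also given relative to the median of all genes. Here and below, values relative to all genes stay similar between scalings largely by construction, so they are no support from the spike-in. RNA-binding regulators had 12 of 23 members down and Syp up (12 and 3 adjusted over the list alone), a median of -0.60 (turned to 0.84 with ERCC totals), or -0.61 relative to all genes and -0.63 under scaling to ERCC totals (adjusted p = 0.000115; adjusted p = 0.402 with an estimated correlation). The fall of shep was 3.07-fold, from 499.2 ± 77.3 CPM. Axon guidance and cell adhesion genes had 13 of 37 down and 18w up (14 and 2 adjusted over the list alone), a median of -0.43 (turned to 1.05 with ERCC totals), or -0.44 relative to all genes and -0.43 under scaling to ERCC totals (adjusted p = 0.00126; adjusted p = 0.402 with an estimated correlation). Ten-a fell 7.32-fold, Ten-m 6.05-fold, the Toll receptor gene Toll-7 3.01-fold and unc-5 3.25-fold. Notch signalling genes had 8 of 23 down and neur up (11 and 1 adjusted over the list alone), a median of -0.72 (turned to 0.77 with ERCC totals), or -0.73 relative to all genes and -0.70 under scaling to ERCC totals (adjusted p = 0.00126; adjusted p = 0.292 with an estimated correlation). The ligand gene Dl fell 1.65-fold, the coactivator gene mam 1.81-fold and the Myc gene dm, a member of the Notch and the insulin lists, 1.82-fold, and the count of 8 was 4 without 84 h replicate 3. Insulin and TOR genes had 6 of 17 down and 0 up (7 and 0 adjusted over the list alone), a median of -0.28 (turned to 1.07 with ERCC totals), or -0.29 relative to all genes and -0.40 under scaling to ERCC totals (adjusted p = 0.00851; adjusted p = 0.188 with an estimated correlation). Pi3K92E fell 2.27-fold and the insulin receptor gene InR 2.02-fold from 1405 ± 218 CPM. This call ended under scaling to ERCC totals (0.597, range 0.00367 to 0.597).

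Stress, ribosomal and identity lists were called as lower at 84 h than at 24 h as well, none with an estimated correlation. Their medians again lay above 0 under scaling to ERCC totals. Heat shock and dissociation stress genes had 7 of 23 down and Hsp67Ba up (10 and 1 adjusted over the list alone), a median of -0.72 (turned to 0.92 with ERCC totals), or -0.73 relative to all genes and -0.55 under scaling to ERCC totals (adjusted p = 0.000582; adjusted p = 0.507 with an estimated correlation). Xbp1, a factor of the unfolded protein response, fell 2.4-fold and the chaperone gene Hsc70-3 1.75-fold, while Hsp67Ba rose 4.44-fold, or 7.46-fold without 24 h replicate 2. The count of 7 was 4 without 24 h replicate 2 or 84 h replicate 2 and 3 without 84 h replicate 3. Cytosolic ribosomal protein genes had 13 of 86 down and 0 up (12 and 0 adjusted over the list alone), a median of -0.19 (turned to 1.28 with ERCC totals), or -0.21 relative to all genes and -0.20 under scaling to ERCC totals (adjusted p = 0.000582; adjusted p = 0.806 with an estimated correlation). RpS7 fell 1.76-fold from 2519 ± 138 CPM and RpL23A 1.72-fold. This call ended without 24 h replicate 3 (0.137) or 84 h replicate 1 (0.0956), turned direction without being called under scaling to ERCC totals (0.653, range 1.08e-07 to 0.653), and the count of 13 was 6 without 84 h replicate 3. Neuroblast identity genes had 4 of 20 down and 0 up (6 and 1 adjusted over the list alone), a median of -0.27 (turned to 1.21 with ERCC totals), or -0.29 relative to all genes and -0.27 under scaling to ERCC totals (adjusted p = 0.0433; adjusted p = 0.422 with an estimated correlation). The Snail-family gene esg fell 9.33-fold from 97.22 ± 18.4 CPM, tll 2.43-fold, SoxN 2.29-fold and Sp1 1.77-fold. This call ended without 24 h replicate 2 (0.0739) and under scaling to ERCC totals (0.556, range 0.0246 to 0.556). As above, this list also holds nerfin-1, pros and ase.

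In all, 1504 genes differed between 24 and 84 h, 651 up and 853 down, 425 and 442 of them by at least 2-fold, with groups that did not overlap in 1403 (10% by chance for unselected genes), and 2530 genes had an unadjusted p under 0.05. The TPM called 995 up and 417 down and scaling to ERCC totals 2343 up and 34 down. The count was 950 without 84 h replicate 2 and 938 without 84 h replicate 3, and 663 without the 2 deepest libraries, 24 h replicates 1 and 2. Of the 53 called genes named in this comparison, 14 turned direction and 12 lost their call under scaling to ERCC totals, and 5 of 52 lost it on the TPM.

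**Figure D2:**
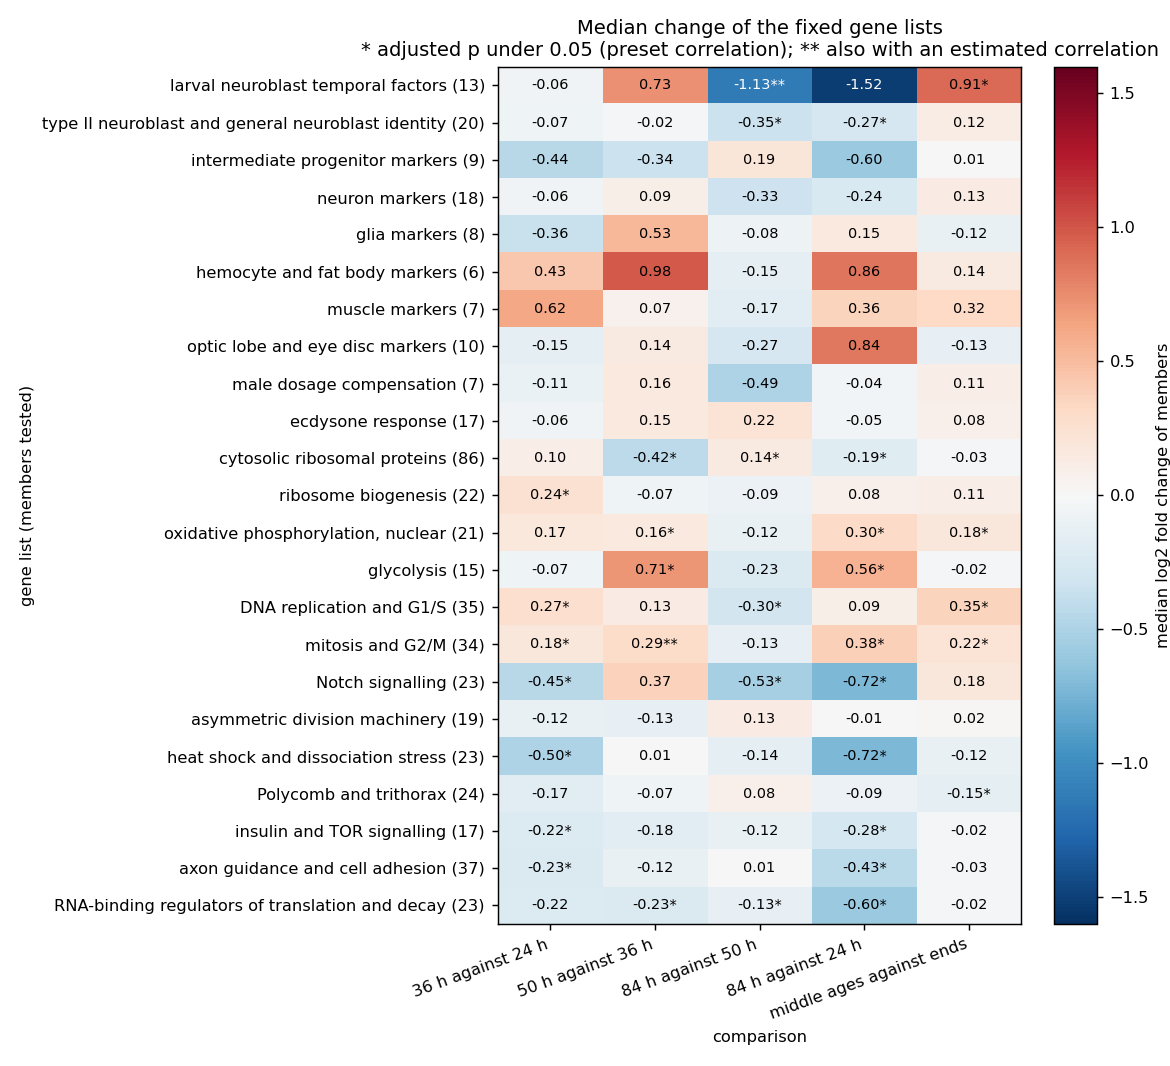
Median log2 fold change of each fixed gene list (rows, with the number of members tested) in the 5 comparisons (columns), in color and printed in each cell. An asterisk marks a list test past the threshold at the preset correlation and a pair of asterisks one that also passes with an estimated correlation, which are mitosis and G2/M at 50 h against 36 h (0.29) and temporal factors at 84 h against 50 h (-1.13), with TMM scaling; under scaling to ERCC totals the medians shift with that of all genes.

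The middle ages (36 and 50 h) were compared with the ends (24 and 84 h) on the mean of log2 levels. This contrast does not require both middle ages to lie beyond both ends. A gene called in it can therefore have an early fall or a late rise instead of a passing high or low. The factors br (log2FC 1.63 ± 0.17, adjusted p = 1.65e-06), D (2.36 ± 0.24, adjusted p = 9.28e-07) and EcR (0.91 ± 0.12, adjusted p = 7.26e-05) were higher at the middle ages. Imp (2.12 ± 0.15) and Syp (2.20 ± 0.17) were higher by this measure too, each being very low at 1 end, and svp was lower (-1.09 ± 0.16). The mean of svp at 36 h (200 CPM) lay above that at 84 h (147.3 CPM), so svp had no passing low at both middle ages. Of 13 temporal factors 7 rose and 1 fell, 8 and 3 adjusted over the list alone, with a median of 0.91 (adjusted p = 2.89e-06; adjusted p = 0.0587 with an estimated correlation). Among the 7, the zinc-finger factor gene mamo rose 5.72-fold to 5.654 ± 3.56 CPM (n = 6) but was not called without 50 h replicate 1 (0.0505, range over all alternatives 0.000214 to 0.341). The factor cas rose 4.2-fold but was called in only 4 of 12 leave-outs, with adjusted p up to 0.123 without 84 h replicate 1 (range 1.37e-31 to 0.803). The ecdysone importer gene Oatp74D rose 10.8-fold, Sip1 5.66-fold to 311.6 ± 76.4 CPM, the glypican gene dally 4.8-fold (7.26-fold without 84 h replicate 1), chn 4.62-fold and the adhesion gene Lac 1.7-fold. The chitin synthase gene kkv fell 6.43-fold, Adgf-A 6.36-fold, CrebA 5.28-fold, trbl, a Tribbles pseudokinase, 1.99-fold and Dscam 1.85-fold.

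DNA replication and G1/S genes rose at the middle ages as a group, with 33 of 35 members above 0, 3 called and 8 adjusted over the list alone, and a median of 0.35 (adjusted p = 1.65e-07; adjusted p = 0.0587 with an estimated correlation). Examples were E2f, 1.44-fold to 958.1 ± 137 CPM (n = 6), and RnrL, 1.5-fold. The mitosis list rose (4 up and 1 down of 34, 10 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.00211; adjusted p = 0.129 with an estimated correlation). CycA rose 1.74-fold and feo fell 1.59-fold, though the feo change turned to 0.10 under scaling to ERCC totals. The mean of feo at 50 h (95.95 CPM) also lay above that at 24 h (57.83 CPM). The 4 that rose were 1 or 2 in 8 of the 12 leave-outs. Nuclear oxidative phosphorylation genes rose (1 of 21 called, 1 adjusted over the list alone, median 0.18, adjusted p = 0.0319; adjusted p = 0.639 with an estimated correlation). Polycomb and trithorax genes fell (2 of 24 called, 3 down and 1 up adjusted over the list alone, median -0.15, turned to 0.54 with ERCC totals, adjusted p = 0.0239; adjusted p = 0.402 with an estimated correlation), ash2 1.7-fold from 132.8 ± 46.2 CPM. The oxidative phosphorylation call ended in 5 leave-outs (range 0.00411 to 0.177), and the Polycomb call without 24 h replicate 2 (0.0525) or 36 h replicate 3 (0.0845) and under scaling to ERCC totals (0.997, range 0.0038 to 0.997). In all, 237 genes passed, 111 up and 126 down, 98 of them by at least 2-fold, and 46 had groups that did not overlap, 6 libraries against 6 (under 1% by chance for unselected genes). The TPM called 66 up and 44 down, upper-quartile factors 127 up and 96 down, and scaling to ERCC totals 76 up and 2 down. The count was 157 without 50 h replicate 3 and 74 with the number of sorted cells as a covariate, where 9 of the 23 genes named here, svp and RnrL among them, were not called.

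Of the remaining lists, 9 were not called in any comparison by camera at the preset correlation, with the lowest adjusted p over the 5 comparisons between 0.0556 and 0.689. Fry called 1 of the 9, the hemocyte and fat body markers, as higher at 50 h than at 36 h (adjusted p = 0.00777) and at 84 h than at 24 h (adjusted p = 0.0026), in a test that makes no comparison with other genes. Its mixed form, for changes either way, called 31 of the 45 tests of these 9 lists, each list at least once. Between 24 and 84 h, intermediate progenitor markers had ey, the Pax6 gene, up (9.06-fold, 3.97 ± 0.704 to 36.3 ± 11.7 CPM) and D and grh down of 9 tested. Neuron markers had nrm up (5.12-fold) and 5 down of 18, with the receptor subunit gene nAcRalpha-34E down 3.43-fold from 166.6 ± 40.2 CPM. The pan-neuronal marker elav had 220.8 ± 25.5 CPM at 24 h and 310.9 ± 53.2 at 84 h (adjusted p = 0.0585). The elav difference passed without 24 h replicate 2 (0.0439) or 84 h replicate 1 (0.0201, range over all alternatives 0.00701 to 1). Glia markers had Eaat1 down of 8, hemocyte and fat body markers Lsp1gamma up of 6, and muscle markers Mhc up and Msp-300 down of 7. Optic lobe and eye disc markers had Optix up and eya, so and hth down of 10, hth 1.85-fold from 363.2 ± 67.6 CPM. Male dosage compensation had msl-1 up and roX2 down of 7. The roX2 fall, 7.97-fold from 7.107 ± 3.17 CPM and 12.6-fold without 84 h replicate 1, was not called without 24 h replicate 3 (0.0881), 84 h replicate 2 (0.081) or 84 h replicate 3 (0.105, range over all alternatives 0.00339 to 0.211). The ecdysone response list had 3 up and 4 down of 17, with a median of -0.05 and a mean of 0.51. The asymmetric division list had stau up and aPKC down of 19, with a median of -0.01 and a mean of 0.02. Polycomb and trithorax genes, not called between 24 and 84 h (adjusted p = 0.813), had 5 up and 3 down of 24, with ash2 up 1.83-fold and ph-p 1.63-fold. Ribosome biogenesis genes (adjusted p = 0.416) had Tif-IA and RpI1 up of 22. Adjusted over the list alone, 2 up and 2 down passed for intermediate progenitors, 2 and 5 for neurons, 0 and 1 for glia, and 2 and 0 for hemocytes and fat body. The counts were 1 and 1 for muscle, 1 and 3 for optic lobe, 1 and 1 for dosage compensation, 3 and 4 for ecdysone response, 1 and 1 for asymmetric division, 5 and 4 for Polycomb and 2 and 0 for ribosome biogenesis. The gene ase, a member of both the neuroblast identity and the intermediate progenitor list, had low means at the 4 ages. They lay between 3.282 ± 1.78 and 7.688 ± 3.24 CPM (adjusted p = 0.427 for any difference), and repo and erm did not pass the filter on low counts. Of the 115 list tests 33 were called at the preset correlation, 2 with an estimated correlation and 21 by fry, 18 of them among the 33. The mixed form of fry called 87.

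The spike-in gave a measure of RNA per cell. The gene counts per ERCC count per sorted cell were 1.46 ± 0.486 at 24 h (SD, n = 3), 2.08 ± 0.258 at 36 h, 3.98 ± 2.37 at 50 h and 2.85 ± 1.26 at 84 h. The geometric means were 1.46-fold, 2.53-fold and 1.88-fold that of 24 h. The ages did not differ beyond the spread between libraries in an exact permutation test over 15400 splits (two-sided, F = 2.94, p = 0.0966). Without 84 h replicate 1, at 1.63 the lowest of its age, the exact p was 0.0412, and over the 12 leave-outs it ranged to 0.212. Scaling by ERCC totals moved the median log2 change of all genes by 0.86 between 24 and 36 h, 1.10 between 36 and 50 h, -0.48 between 50 and 84 h, 1.48 between 24 and 84 h and 0.67 for the middle ages against the ends. Changes given above, unless another scaling is named, rest on TMM factors. They are therefore relative to the bulk of the genes tested, neither to total RNA nor per cell.

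**Figure D3:**
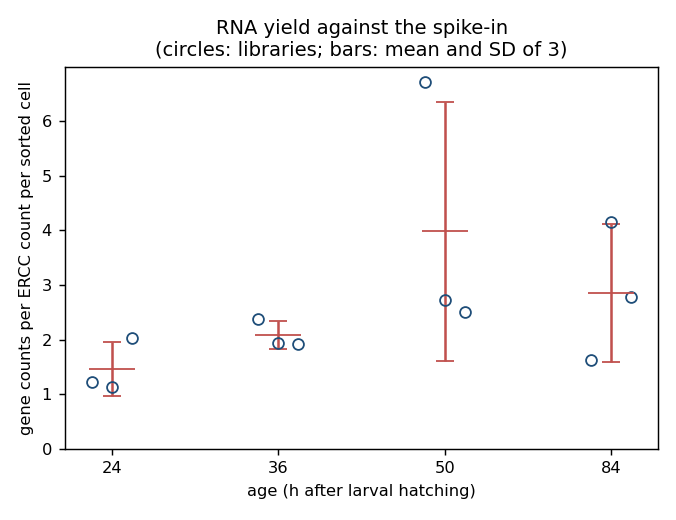
Gene counts per ERCC count per sorted cell on a linear axis from 0, against age in hours, with circles for the 12 libraries and bars for the mean and SD of 3. The 50 h libraries spread widest, with 1 at 6.71.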

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

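The alternatives without the 3 most abundant RNAs, with counts thinned to the shallowest library and without both deep 24 h libraries were chosen after seeing the data, and the others before. The spike-in alternative on the TPM was not run, since the TPM table holds no ERCC rows. For changes in number below the cause was not tested, except where the test itself asks for a larger change (a 2-fold threshold).

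Of 156 called changes of named genes in the 5 comparisons, scaling to ERCC totals ended 68 calls and turned 19, and scaling to ERCC totals times sorted cells ended 57 and turned 18. The covariate for sorted cells ended 24, glmTreat against a 2-fold change 90, limma-voom 7, and leaving out both deep 24 h libraries 21. DESeq2 size factors and upper-quartile factors ended 1 each. DESeq2, no filter on low counts, the replicate block, leaving out the 3 most abundant RNAs and thinned counts ended 0, and so did a minimum of 10 CPM for 149 tested there. Of 147 found in the TPM table, log2(TPM + 1) ended 26 and log2(TPM + 0.1) 32, and of 148 without a filter 30 ended. A fit of only the 2 groups ended 6 of 132. Leaving out 1 library ended 1 to 12, a low number by choice, since the genes described were preferred for calls kept in leave-outs. Of the 55 called changes that the rule gave and the text does not describe it ended 6 to 23, and of all 2396 called changes 263 to 846 (11 to 35.3%).

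The turned changes, as log2FC under scaling to ERCC totals and to ERCC totals times sorted cells, were those of svp (0.16, 0.18), rin (0.04, 0.06), RpL22 (0.4, 0.42) and RpLP0 (0.47, 0.51) between 36 and 50 h. Between 24 and 84 h they were grh (0.86, 0.78), tll (0.37, 0.28), SoxN (0.3, 0.22), Sp1 (0.59, 0.51), dm (0.61, 0.53), mam (0.54, 0.46) and Dl (0.83, 0.75). The others there were Pi3K92E (0.24, 0.16), InR (0.45, 0.38), RpS7 (0.62, 0.54), RpL23A (0.64, 0.57), Xbp1 (0.13, 0.05), Hsc70-3 (0.79, 0.7) and hth (0.55, 0.47). For the middle ages against the ends it was feo (0.1, ERCC totals). All 37 values stayed on the same side of the median of all genes as with TMM. This follows largely by construction, since these scalings move all genes of a comparison by about the same amount. It is therefore no separate support from the spike-in for the changes under TMM.

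The counts of genes called, 1556 for any age difference, then 72, 339, 244, 1504 and 237 in the order of the report, moved by over 1.5 times as follows. Scaling to ERCC totals gave 2780, 20, 148, 33, 2377 and 78, and times sorted cells 3114 for any age, 23, 41 for 84 h against 50 h, 2792 for 84 h against 24 h and 75 for the middle ages. DESeq2 gave 198, 528 and 383 for 36 h against 24 h, 50 h against 36 h and the middle ages, and no filter on low counts 252, 536 and 426. On log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter, 36 h against 24 h gave 34, 31 and 24, 84 h against 50 h 119, 108 and 104 and the middle ages 110, 81 and 97, and the last gave 184 for 50 h against 36 h. The sorted-cell covariate gave 21 for 36 h against 24 h and 74 for the middle ages. The glmTreat test gave 3, 21, 24, 232 and 18, and a 2-fold range of group means 997 for any age. A fit of only the 2 groups gave 578 for 50 h against 36 h. Leaving out both deep 24 h libraries gave 26 for 36 h against 24 h, 571 for 50 h against 36 h, 663 for 84 h against 24 h and 147 for the middle ages. Of the 33 list tests called, 2 were also called with an estimated correlation and 18 by fry, which called 21 in all.

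Leaving out 1 library gave 1203 to 1739 genes for any age, 29 to 180 for 36 h against 24 h, 157 to 448 for 50 h against 36 h, 112 to 266 for 84 h against 50 h, 938 to 1598 for 84 h against 24 h and 157 to 331 for the middle ages. It gave 28 to 39 list tests and an exact p of 0.0412 to 0.212 for the spike-in ratio, which was 0.0942 without division by sorted cells. The libraries that moved a count by over 1.5 times were 24 h replicates 2 (40) and 3 (180) and 36 h replicate 3 (29) for 36 h against 24 h. For 50 h against 36 h they were 36 h replicate 2 (157) and 50 h replicates 1 (186), 2 (211) and 3 (199). For 84 h against 50 h they were 50 h replicates 2 (112) and 3 (133) and 84 h replicates 2 (133) and 3 (121), for 84 h against 24 h 84 h replicates 2 (950) and 3 (938), and for the middle ages 50 h replicate 3 (157).

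With the replicate number as a block the count for 36 h against 24 h was 119, the others 1681 for any age difference, 447, 271, 1615 and 296. The labels do not say that numbers pair libraries across ages. Same-number correlations of residuals ran from -0.09 to 0.16, with 2 of 18 over 0.1, and 6 of 12 libraries correlated best with their own number. Different-number correlations ran from -0.13 to 0.13. The highest of each kind joined 36 h replicate 3 with 50 h replicate 3 (0.16) and with 84 h replicate 2 (0.13). Whether some libraries are paired across ages is thus not settled.

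Thinning to the shallowest library gave 1534 genes for any age difference and 70, 357, 241, 1473 and 234 in the comparisons, all within 1.5 times. Apart from 24 h replicates 1 and 2 the libraries held 4512102 to 5765181 gene counts, so thinning took little from them. It also cannot show what more depth would add, so whether depth limits the calls was not tested. Simulated counts of this depth, spread and number of libraries do not part the 3. In them edgeR found 49 to 52 of 100 genes changed 2-fold in the 3 against 3 comparisons. Of genes changed 4-fold it found 87 to 97 of 100. The changed genes were drawn from those with a mean of at least 10 CPM.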

Other observations

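The tests of a deviating library for the ribosomal protein genes and of RNA of younger neuroblasts and the markers of each single cell type in 84 h replicate 1 were chosen after the result was seen. The genes of the next paragraph were chosen after their values were seen.

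Of the circadian clock genes looked at, Clk and cry were not among the genes tested. Of the 6 tested, the repressor gene vri rose between 24 and 84 h from 46.63 ± 8.37 to 222.4 ± 58 CPM (SD, n = 3, log2FC 2.26 ± 0.23, adjusted p = 3.18e-07). Pdp1 fell from 98.23 ± 7.98 to 27.16 ± 5.4 (-1.86 ± 0.21, adjusted p = 1e-06) and cwo from 206.4 ± 16.6 to 65.82 ± 4.61 (-1.65 ± 0.21, adjusted p = 5.06e-06). Of the others cyc was lower (-1.88 ± 0.65, adjusted p = 0.0458, but 0.16 for any difference between ages, and up to 0.196 in the 9 of 12 leave-outs that ended the call). Between 24 and 84 h tim (adjusted p = 0.511) and per (adjusted p = 0.923) did not pass. However, tim passed for any difference between ages (adjusted p = 0.00578), with 12.05 ± 7.89 CPM at 50 h against 0.9622 ± 0.686 at 36 h, though not without 50 h replicate 1 (0.0654) or 2 (0.0687), and per did not (0.49). Of the genes of glycogen and phosphagen metabolism looked at, GlyS and AGBE were not among the genes tested. Of the 4 tested, 3 rose and UGP did not pass (0.24 ± 0.71, adjusted p = 0.855). The glycogen phosphorylase gene GlyP rose to 350.5 ± 11.2 CPM (2.60 ± 0.18, adjusted p = 8.86e-10), Glycogenin to 415.1 ± 5.64 (2.23 ± 0.16, adjusted p = 1.2e-09) and the arginine kinase gene Argk to 345.7 ± 26.2 (2.52 ± 0.19, adjusted p = 2.73e-09). The long noncoding RNA cherub (CR43283) fell from 135100 ± 38400 to 50390 ± 23000 CPM (-1.42 ± 0.29, adjusted p = 0.00159). CR31386 was highest at 36 h, with 1094 ± 206 CPM against 283.9 ± 93.5 at 24 h and 235.2 ± 67.5 at 84 h (adjusted p = 4.63e-07 for any difference). Of the other noncoding RNAs looked at, pncr002:3R rose between 24 and 84 h (4.8 ± 0.21, adjusted p = 1.44e-13). CR43334 (-1.27 ± 0.21, adjusted p = 0.000155) and CR44024 (-1.11 ± 0.21, adjusted p = 0.000674) fell. Between these ages roX1 (adjusted p = 0.11) and Hsromega (adjusted p = 0.563) did not pass.

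Cytosolic ribosomal protein genes were lower at 50 h than at 36 h, with a list median of -0.42. Their transcripts are short, and genes matched on length and expression had a median of -0.04 (95% of 1000 draws between -0.08 and 0.12), which argues against a bias by transcript length as the whole cause. Leaving out each of the 6 libraries gave medians of -0.53 to -0.34, so no single one of them made the difference, and the mean log2 CPM of the list was 9.09, 9.02 and 9.31 in the 36 h libraries and 8.79, 8.53 and 8.8 in the 50 h libraries. A difference with age was not tested apart from these and stays open.

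Heat shock and dissociation stress genes were lower at 84 h than at 24 h, the 7 called members by a median of -1.26. With a score of heat-inducible genes outside these 7 as a covariate the median was -0.55 (median SE 0.28) and Xbp1 alone kept its call (adjusted p = 0.00371), while the genes called in all went from 1504 to 637. Of the lost calls, that of Mmp1 went with a larger change, from -2.49 ± 0.82 to -3.32 ± 1.12. The other lost calls went with smaller changes, such as puc from -0.90 ± 0.20 to -0.67 ± 0.28 and DnaJ-1 from -1.72 ± 0.43 to -0.48 ± 0.24. The bound set beforehand for handling stress was a median above -0.63, and -0.55 passed it by less than its SE. The score itself was 5.62, 6.97 and 7.25 in the 24 h libraries and 4.93, 3.52 and 2.71 in the 84 h libraries. It also varied within ages, at 7.3, 4 and 6.31 at 36 h and 5.25, 4.9 and 6.97 at 50 h. Handling stress that varied between libraries and a difference with age therefore cannot be told apart here, also since the score differed between 24 and 84 h.

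The 84 h replicate 1 library lay nearer to the 50 h libraries than the other 84 h libraries, 32.6% of the way over the 195 genes called without it, against 2.3% for replicate 2 and -1.5% for replicate 3 over their own sets of 133 and 121 genes. Its cherub (CR43283) was 76600 CPM against 33410 and 41150, its Sip1 44.39 against 19.53 and 14.59 and its ytr 2158 against 310.3 and 322.9. Admixed RNA of 50 h neuroblasts would bring Imp in the same share, but Imp gave 1.18% (2 SD 0.638) where the 22 genes falling at least 4-fold gave a median of 12%, which argues against it as the whole source. RNA from cells of another type stays open, since the planned median over 39 markers (log2 excess 0.29, bootstrap SE 0.27) pools 4 types, so that cells of 1 type would hardly move it, and by type it was 0.31 (SE 0.29) for neurons, -0.15 (0.45) for glia, -0.03 (0.62) for hemocytes and fat body and 0.76 (0.75) for muscle, the last too wide on 7 markers to lie below the bound of 1. A younger developmental stage of the animals in this pool was not tested and stays open as well.

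Other splits of the libraries were compared for each count. For any age 1 of 100 drawn splits, the real one, gave as many as 1556 genes, the highest other being 137. For the middle ages against the ends 1 of 100 gave as many as 237, the highest other being 22. The share was thus 1 of 100 for both counts. Every other split mixes libraries of different ages, so a passing high or low was not tested apart from other age differences. Chance differences between pools of animals are not covered either, since libraries of one age may share a dissection. For the list tests 4 of 100 gave as many as 33, the highest other being 38, a share under 0.05, but the other splits called 5 to 38 with a median of 18. Calls of single lists at the preset correlation are thus common under shuffled ages, and only the number of them was tested here. In the 4 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There 1 of 10 gave as many as the real 72 (highest other 1), 1 of 10 as many as 339 (5), 1 of 10 as many as 244 (0) and 1 of 10 as many as 1504 (1).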
